A study of Mus musculus with 10 samples.

How the data were processed

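The series holds 10 libraries of transferred SMARTA CD4 T cells, 6 TOX KO and 4 TOX WT, sorted from the tumour-draining lymph node. Per the labels' protocols, RNA from cells sorted into Trizol was amplified with the SMART-seq v4 kit (12 cycles from 2 to 10 ng of RNA), libraries were made from 10 ng of cDNA with 8 PCR cycles, and sequencing was paired end with 50 bp reads on a HiSeq instrument. The deposited values are counts of read pairs per gene, made by the authors with featureCounts 1.6.2 on the GENCODE M17 annotation of GRCm38.p6, per the file headers. The commands in the file headers set no strand option and did not count reads that match several places, so overlapping genes on opposite strands share uncertainty and near-identical copies are undercounted. FastQC and STAR are named in the submitters' processing notes without a version. The tables hold 53656 genes each and were not normalized.

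From these counts, libraries were scaled with TMM factors, genes were kept by edgeR's filterByExpr, and KO was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, limma 3.58.1) with genotype as the only term. Fold changes are coded KO minus WT on the log2 scale, SE is the fold change over the square root of the F statistic, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values use the TMM-scaled library sizes, and log2 CPM adds a prior count of 2. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 28 lists, beside camera with an estimated correlation and fry. At the preset correlation 1 to 15 lists were also called when the libraries were split into groups that mix the genotypes. Such a call alone is therefore weak evidence. The share of counts on Trbv13-1 and on the Trav14 family was compared by an exact permutation test, and chromosome neighbourhoods of 10 Mb by Fisher's exact test. Depth was 31939816 to 55784453 counts per library. Libraries of 1 group were compared pairwise by a chi-square of their counts, which left no pair within sampling noise.

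The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Tox; the genes of the sort markers and Ptprc; 12 fixed T cell genes; up to 3 called members per list; the 10 largest rises and 10 largest falls among named protein-coding genes with a mean of at least 8 CPM and no overlap of the groups; and the 2 most abundant markers of each other cell type. Other members of a list that passed were named after their values were seen. Some genes that the rule names are not reported here.

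Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom with and without quality weights, robust fits, a threshold of 0.01, a fold above 1.5, leaving out each library, blocks by replicate or library number, 1 surrogate variable (sva 3.50.0), thinning to the smallest library, removal of the gene length trend, and restricted gene sets. Added after the data were seen were a term for the library set (numbers 1 to 3 against 4 to 8, which differ in genes detected), each set alone, removal of the GC trend with GC content from GENCODE M21 transcripts (11629 of 14214 tested genes had a value), scaling to 8 T cell receptor complex genes, and the mean log2 CPM of the B cell list as a term.

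The procedure was tested on simulated data with the libraries' own means, sizes and dispersions. Each of 3 runs over 14214 genes held 50 changed genes at each fold. Changed genes had a mean of at least 8 CPM, rises and falls were balanced, and each gene was drawn independently of the others. For this comparison it recovered 0% of genes changed 2-fold, 16% at 4-fold, 45.3% at 8-fold and 60.7% at 16-fold, and 2.66% of its calls were false. Genes that did not pass may therefore have changed by several fold. The data hold more falls than rises and genes that move together, so the simulated share of false calls may not carry over to them. Recovery of genes below 8 CPM was not tested.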

Results

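Gene expression was measured by RNA sequencing in 10 libraries of CD4 T cells sorted from the lymph node draining a mouse melanoma. The cells carried the SMARTA T cell receptor, a transgenic receptor that recognises the GP61 peptide of lymphocytic choriomeningitis virus, and were either TOX wild type (WT, n = 4) or TOX knockout (KO, n = 6). TOX is a nuclear protein of the HMG-box family that is known for its part in T cell development and in T cell exhaustion. Naive cells of both genotypes went into B6 mice that had received cytoxan (cyclophosphamide) and bore B16-GP61 melanoma, a B16 line carrying the peptide, and were sorted 11 days later. The sort gates in the labels differed with genotype: the KO cells were taken as PD1, LAG3 and CD39 low, and the WT cells as high for all 3 proteins. The congenic marker differed as well: KO cells were sorted as Ly5.1 positive and Ly5.2 negative, and WT cells as positive for both. Genotype and gate therefore cannot be told apart. The labels name replicates but not the animals behind them, so p-values measure the spread between these libraries, which may be partly technical. The deposited tables gave 31939816 to 45481478 counts per WT library and 36028980 to 55784453 per KO library over 53656 genes.

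Tox, the targeted gene (GRCm38 chromosome 4, 6686353 to 6991557, minus strand), was lower in every KO library than in every WT library. It stood at 236 ± 88.0 CPM (SD, n = 4) in WT and 31.0 ± 20.8 CPM (SD, n = 6) in KO, a log2 fold change of -2.93 (SE 0.48, edgeR adjusted p = 0.010). The lowest WT library held 170 CPM and the highest KO library 68.0 CPM, so Tox reads were still present in KO. Which part of the gene was removed is not given in the labels, and reads outside a deleted part would still be counted. Pdcd1, which encodes PD1, was also lower in KO without overlap, at 431 ± 74.1 CPM (SD, n = 6) against 1092 ± 353 CPM (SD, n = 4), a log2 fold change of -1.34 (SE 0.24, edgeR adjusted p = 0.016). That call was lost in 4 of the 10 fits without 1 library (WT replicates 2 and 4, KO replicates 2 and 3), where the largest adjusted p was 0.077 without WT replicate 2. Within library numbers 4 to 8 Pdcd1 was -1.19 (edgeR adjusted p = 0.10) and within numbers 1 to 3, which hold 1 WT library, it was -1.43 (0.064). Lag3 did not follow its gate: the mean was 206 ± 137 CPM in KO and 93.1 ± 152 CPM in WT (log2 fold change 1.15, SE 1.01, edgeR adjusted p = 0.59). The WT mean rested on WT replicate 1 with 320 CPM; the other WT libraries held 7.53 to 36.2 CPM, below every KO library (83.4 to 427 CPM), and without WT replicate 1 Lag3 was higher in KO (log2 fold change 3.55, edgeR adjusted p = 0.022). Entpd1, which encodes CD39, was at 6.44 ± 7.76 CPM in KO and 71.8 ± 51.1 CPM in WT, a difference that did not pass the test (log2 fold change -3.48, edgeR adjusted p = 0.21). Entpd1 passed within library numbers 4 to 8 (-2.88, edgeR adjusted p = 0.049) and with DESeq2 (-3.55, adjusted p = 0.043).

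**Figure D1:**
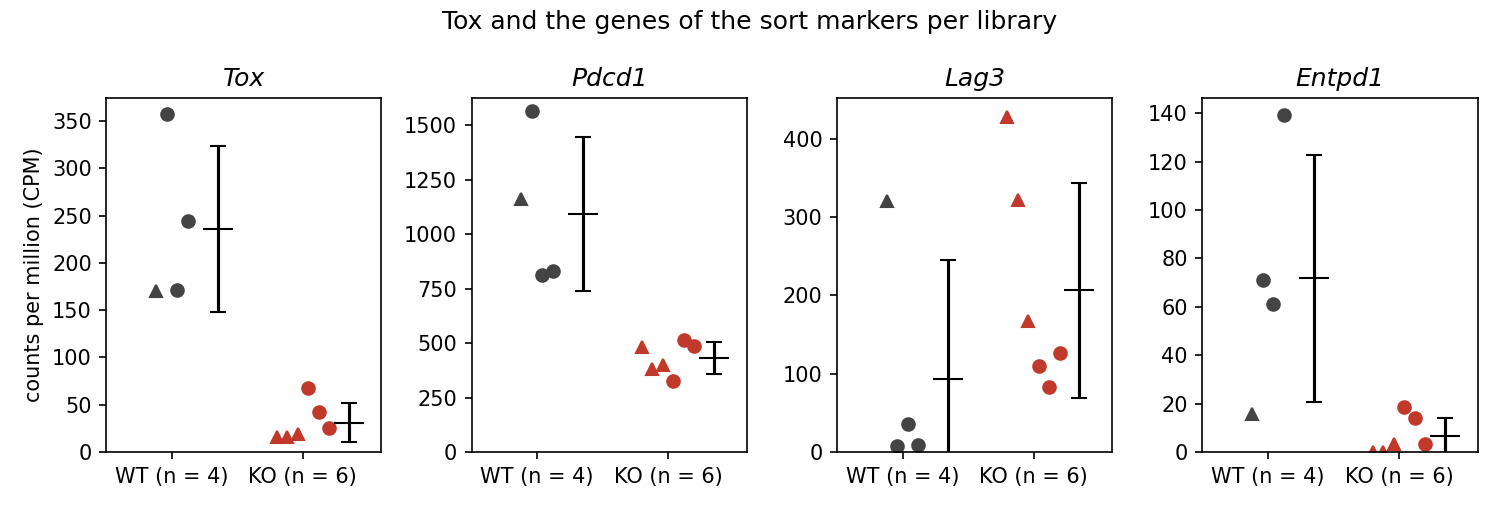
CPM (vertical axes) of Tox and of the genes behind the sort markers PD1, LAG3 and CD39 (Pdcd1, Lag3, Entpd1) in each library, with the mean and SD of each genotype as black bars; triangles are library numbers 1 to 3 and circles 4 to 8. Tox lies between 170 and 357 CPM in WT and between 15.3 and 68.0 CPM in KO.

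Of 14214 genes tested, 61 were higher and 384 lower in KO than in WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The genes that were lower included many that belong to B cells: 106 of them were immunoglobulin genes and all 10 tested genes of the MHC class II pathway were among them. Slamf8 had no count in any KO library and 4418 counts in WT, so it was at least 2635-fold lower in KO against a floor of 3 counts over the group. Cx3cr1, a chemokine receptor, Xcl1, a chemokine, and Lyz1, a lysozyme gene on the myeloid marker list, had log2 fold changes of -9.17, -8.58 and -7.10 (edgeR adjusted p = 0.0042, 0.0092 and 0.0092). They kept their calls without any 1 library. The 24 tested myeloid and dendritic cell markers had a median of -4.67, so such falls may come partly from RNA of other cells, which was not tested. The counts depended on single libraries. Without WT replicate 1, 2, 3 or 4 the genes higher numbered 443, 14, 307 and 10, and without KO replicate 1, 2, 3, 5 or 6 they numbered 25, 25, 38, 40 and 39. The genes lower numbered 1201, 222 and 143 without WT replicate 1, 2 or 4. Of 55 genes that met the naming rule and passed the test, some of which are not described here, 21 passed in every fit without 1 library.

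The TH1 effector list, which is closest to the study's question of what TOX does in TH1 cells, was lower in KO. Of 28 members tested, 7 fell, 0 rose and 21 did not pass the test. Those that fell included Cxcr3, Ccl3, Ccl4, Ccl5, Ly6c2 and Nkg7. The calls on Cxcr3, Ccl3 and Ccl4 were lost in 6, 6 and 7 of the 10 fits without 1 library (adjusted p up to 0.094, 0.12 and 0.14), and that on Nkg7 without WT replicate 4 (0.053). Adjusted over the list alone, 11 fell. Ly6c2, a surface protein of effector T cells and monocytes, stood at 18.3 ± 4.20 CPM in KO and 271 ± 197 CPM in WT (log2 fold change -3.88, SE 0.43, edgeR adjusted p = 0.0021). Ccl5, a chemokine, stood at 4.24 ± 3.70 CPM in KO and 97.3 ± 44.8 CPM in WT (log2 fold change -4.52, SE 0.72, edgeR adjusted p = 0.0092). Tbx21, which encodes the TH1 regulator T-bet, was at 20.6 ± 25.002 CPM in KO and 26.7 ± 41.3 CPM in WT (log2 fold change -0.38, SE 1.11, edgeR adjusted p = 0.88). Its WT mean rested on WT replicate 1 with 88.3 CPM against 2.68 to 12.4 CPM in the other WT libraries. Without that library the direction turned to 1.74 (edgeR adjusted p = 0.28). Ifng, the TH1 cytokine, stood at 2.87 ± 2.34 CPM in KO and 41.4 ± 27.0 CPM in WT and did not pass (log2 fold change -3.85, edgeR adjusted p = 0.089). Ifng passed with DESeq2 (adjusted p = 0.0025) and within library numbers 4 to 8 (-3.06, edgeR adjusted p = 0.036). Cxcr6 did not pass either (log2 fold change -2.60, edgeR adjusted p = 0.27). Within library numbers 4 to 8 it passed (-1.74, edgeR adjusted p = 0.045). The list's median log2 fold change was -2.58 (camera adjusted p = 5.2e-07, adjusted p = 0.066 with an estimated correlation). Within library numbers 4 to 8 (3 KO, 3 WT) the median was -1.87, and within numbers 1 to 3 (3 KO, 1 WT) it was -2.05. Immunoglobulin genes took 0.815 to 16.7% of the counts in the WT libraries and 0.0835 to 0.187% in the KO libraries.

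**Figure D2:**
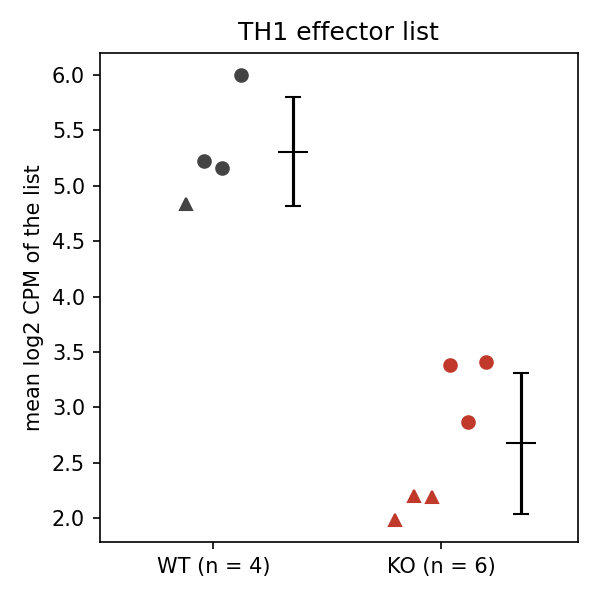
Mean log2 CPM of the 28 tested genes of the TH1 effector list (vertical axis) in each library, with the mean and SD of each genotype as black bars; triangles are library numbers 1 to 3 and circles 4 to 8. The 4 WT libraries lie between 4.84 and 6.00 and the 6 KO libraries between 1.98 and 3.41.

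Genes of cytotoxic granules were lower in KO as a list. Of 18 members, 4 fell (Ctsw, Prf1, Klrd1 and Nkg7), 0 rose, and 10 fell when adjusted over the list alone (median log2 fold change -3.21, camera adjusted p = 3.5e-07, adjusted p = 0.061 with an estimated correlation). Ctsw, a cysteine protease of cytotoxic cells, stood at 31.2 ± 5.04 CPM in KO and 177 ± 43.6 CPM in WT (log2 fold change -2.50, SE 0.26, edgeR adjusted p = 0.0014). Gzmb, which encodes granzyme B, was at 1.31 ± 1.65 CPM in KO and 41.9 ± 37.7 CPM in WT (log2 fold change -4.99, SE 1.35, edgeR adjusted p = 0.081). Gzmb passed with DESeq2 (adjusted p = 7.3e-04) and without WT replicate 1 (edgeR adjusted p = 0.032). The call on Nkg7 was lost without WT replicate 4 (adjusted p = 0.053), and those on Prf1 and Klrd1 in 7 of 10 fits without 1 library (adjusted p up to 0.13 and 0.17). The list's median was -2.41 within library numbers 4 to 8 and -1.64 within numbers 1 to 3, and with the B cell score as a term its call was lost (-1.17, camera adjusted p = 0.068). The immunoglobulin share also differed between the genotypes, at a mean of 8.13% of counts in WT and 0.125% in KO. Within WT, granule genes differed in how they followed that share. WT replicate 1 had the lowest share of the WT libraries (0.815%). It had the highest Nkg7 (1640 CPM), Ctsw (217 CPM) and Prf1 (52.7 CPM), but the lowest Gzmb (5.87 CPM). Gzmb ranked in the same order as the share across the WT libraries. WT replicate 4, with the highest share, also exceeded WT replicates 2 and 3 for Nkg7, Ctsw and Prf1. Whether RNA of other cells adds to these falls was not settled.

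Cell cycle genes were lower in KO as well. Of 40 members of the proliferation list, 8 fell (Cdk1, Birc5, Aurka, Ccnb1, Tyms, Tk1, Hmgb2 and Stmn1) and 0 rose; adjusted over the list alone, 26 fell. The median log2 fold change was -2.79 (camera adjusted p = 3.0e-12, adjusted p = 0.066 with an estimated correlation). Cdk1, the kinase that drives mitosis, stood at 10.1 ± 5.77 CPM in KO and 131 ± 110 CPM in WT (log2 fold change -3.70, SE 0.62, edgeR adjusted p = 0.011). Its call held without any 1 library, while each of the other 7 was lost in at least 1 such fit. The adjusted p without WT replicate 4 was 0.054 for Birc5, 0.075 for Aurka, 0.13 for Ccnb1, 0.092 for Tyms, 0.093 for Tk1, 0.11 for Hmgb2 and 0.075 for Stmn1. The list's median was -1.46 within library numbers 4 to 8, -2.91 within numbers 1 to 3 and -1.82 without WT replicate 1. With the B cell score as a term it was -4.05 (camera adjusted p = 4.8e-17), while 0 members were called. The scores of the genotypes do not overlap (2.08 to 4.25 in KO, 7.33 to 9.56 in WT), and edgeR called 0 genes with that term. That fit therefore cannot tell RNA of B cells from genotype. The myeloid marker list was also lower in KO, at a mean log2 CPM of 0.31 ± 1.36 against 5.13 ± 1.31 in WT. That is a difference between the genotypes. Within WT the lowest myeloid mean was in WT replicate 1 (3.30) and the lowest proliferation mean in WT replicate 2 (4.70).

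Chemokine receptor and trafficking genes showed 7 falls (Ccr6, Ccr8, Cxcr3, Cxcr5, Cx3cr1 and Itgae among them) and 0 rises among 25 tested. Adjusted over the list alone, 11 fell and 2 rose (median log2 fold change -1.98, camera adjusted p = 1.7e-06, adjusted p = 0.079 with an estimated correlation). The median was -1.13 within library numbers 4 to 8 (camera adjusted p = 4.3e-06) and -1.24 without WT replicate 4 (9.9e-07). Within numbers 1 to 3, which hold 1 WT library, it was -0.66. The call on Ccr6 was lost in 8 and that on Itgae in 2 of the 10 fits without 1 library (adjusted p up to 0.13 and 0.060). Cxcr5, the receptor that guides cells to follicles, stood at 47.5 ± 27.96 CPM in KO and 551 ± 318 CPM in WT (log2 fold change -3.54, SE 0.59, edgeR adjusted p = 0.010). Its exons overlap Bcl9l on the other strand, and the counting did not use strand. Within WT, Cxcr5 was lowest in WT replicate 1 (211 CPM, others 473 to 977 CPM). That library also had the lowest mean log2 CPM of B cell and plasma cell markers (7.33, others 9.30 to 9.56). Whether RNA of B cells adds to this fall was not settled. The T follicular helper list had 3 falls among 18 (Cxcr5, Pdcd1, Pou2af1), 5 falls and 2 rises over the list alone, a median log2 fold change of -0.68, camera adjusted p = 0.015 and adjusted p = 0.41 with an estimated correlation. Its call was lost within library numbers 4 to 8 (median -0.15, camera adjusted p = 0.45) and with the GC trend removed (-0.40, 0.099). It was also lost without KO replicate 1 (-0.49, 0.056) or WT replicate 2 (-0.37, 0.053). Of the 3 falls, Pdcd1 encodes the sort marker PD1, and the T follicular helper list was not tested without it. With the B cell score as a term the list kept its call (-1.21, camera adjusted p = 0.019), while 0 members were called. The scores of the genotypes do not overlap, so that fit cannot tell RNA of B cells from genotype. Pou2af1, a coactivator also used by B cells, had a log2 fold change of -3.19 (edgeR adjusted p = 0.0030). Bcl6 did not pass (log2 fold change -1.85, edgeR adjusted p = 0.37), with 0.12 CPM in WT replicate 1 and 43.6 to 73.6 CPM in the other WT libraries. Without WT replicate 1 it fell (-2.26, edgeR adjusted p = 0.024). Within library numbers 4 to 8 it was -1.66 (0.044) and within numbers 1 to 3, where WT replicate 1 is the only WT library, it was 5.87 (0.090). The TH2 and TH17 list had 4 falls among 12 (Ccr8, Ccr6, Tmem176a, Tmem176b), both over all genes and over the list alone, camera adjusted p = 8.4e-05 and adjusted p = 0.079 with an estimated correlation. With the B cell score as a term this list lost its call and its median turned to 0.37 (camera adjusted p = 0.39), and the chemokine receptor list lost its call too (-0.57, camera adjusted p = 0.085). Tmem176a and Tmem176b overlap each other on opposite strands, so their reads cannot be told apart here, and the call on Tmem176b was lost without WT replicate 4 (0.051). The regulatory T cell list was not called (2 of 17 fell, Itgae and Capg; 5 fell and 1 rose over the list alone; camera adjusted p = 0.14), the call on Capg was lost without WT replicate 4 (adjusted p = 0.067), and Foxp3 did not pass (log2 fold change -3.38, edgeR adjusted p = 0.30). With limma-voom Foxp3 passed (-6.67, adjusted p = 0.036). These falls were in the KO libraries, whose B cell and plasma cell list had a mean log2 CPM of 3.61 ± 0.85 against 8.90 ± 1.05 in WT.

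Coinhibitory receptor genes went both ways. Of 16, 2 fell (Pdcd1 and Tigit) and 1 rose (Vsir); over the list alone 4 fell and 2 rose (median log2 fold change -1.26, camera adjusted p = 0.015, adjusted p = 0.22 with an estimated correlation). Within library numbers 1 to 3, which hold 1 WT library, the median of the coinhibitory receptors list was -0.26. The call on that list was lost within numbers 4 to 8 (median -1.14, camera adjusted p = 0.26). It was also lost with the GC trend removed (-1.17, 0.058), with the B cell score as a term (-0.77, 0.23) and without WT replicate 1 (-1.30, 0.16). The immunoglobulin share of these libraries was 0.125 ± 0.0358% in KO and 8.13 ± 6.52% in WT. Without the 3 gate genes the list of 13 had a camera p of 0.019 and a p of 0.16 with an estimated correlation. The calls on Tigit and Vsir were lost in 6 and 7 of the 10 fits without 1 library, with adjusted p up to 0.079 and 0.14 without WT replicate 4. Among 18 exhaustion-associated regulators, Cd38 fell and Nr4a1 and Egr3 rose, with 6 falls and 5 rises over the list alone (camera adjusted p = 0.99). Cd38, an ectoenzyme also found on B cells, stood at 9.73 ± 2.90 CPM in KO and 276 ± 184 CPM in WT (log2 fold change -4.83, SE 0.62, edgeR adjusted p = 0.0031). Within WT, Cd38 was lowest in WT replicate 1 (28.4 CPM, others 283 to 472 CPM). That library also had the lowest mean log2 CPM of B cell and plasma cell markers (7.33, others 9.30 to 9.56). Tox2, a relative of Tox, did not pass (log2 fold change -3.62, edgeR adjusted p = 0.17). Its fold rested on WT replicate 1 with 592 CPM against 3.89 to 41.0 CPM in the other WT libraries. Without WT replicate 1 it was -0.43 (edgeR adjusted p = 0.78).

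Immediate early genes, which respond within minutes to receptor signals, were higher in KO as a list. Of 25, Egr3 and Nr4a1 rose and Ier3 fell, with 4 rises and 1 fall over the list alone (median log2 fold change 1.25, camera adjusted p = 5.7e-04, adjusted p = 0.079 with an estimated correlation). Nr4a1 stood at 609 ± 279 CPM in KO and 158 ± 68.6 CPM in WT (log2 fold change 1.94, SE 0.41, edgeR adjusted p = 0.031), and Egr3 at 37.1 ± 17.3 against 5.06 ± 3.16 CPM (log2 fold change 2.87, SE 0.59, edgeR adjusted p = 0.026). Their calls were lost in 4 and 5 of the 10 fits without 1 library, with adjusted p of 0.099 and 0.11 without WT replicate 4, and that on Ier3 in 5 (up to 0.075). T cell receptor signalling genes were higher as a list (1 of 22 rose, Cd5; 2 rose and 1 fell over the list alone; camera adjusted p = 0.0053, adjusted p = 0.061 with an estimated correlation). Cd5, a brake on receptor signals, stood at 1045 ± 234 CPM in KO and 334 ± 77.6 CPM in WT (log2 fold change 1.65, SE 0.26, edgeR adjusted p = 0.0090). Genes of the receptor complex did not pass. Of 8, 7 had positive log2 fold changes, among them 0.89 for Trac and 0.72 for Cd3e, and Trbc1 had -0.17. Scaling every library to 8 receptor complex genes shifted the median of all genes by -0.76 and left 20 genes higher and 1671 lower, so that 1.18% of calls were higher against 13.7% with TMM. The median of the immediate early list was then 0.48 (camera adjusted p = 3.0e-04). The T cell receptor signalling list cannot be read with this scaling, since 5 of the 8 scaling genes are members of it. Cd5, Egr3, Nr4a1 and Vsir did not pass with that scaling, with log2 fold changes of 0.86, 1.99, 1.33 and 0.46 (edgeR adjusted p = 0.16, 0.095, 0.087 and 0.45). With the B cell score as a term neither the immediate early list nor the T cell receptor signalling list was called (medians 0.88 and 0.49 against 1.25 and 0.72, camera adjusted p = 0.34 and 0.74). The B cell and plasma cell list moved the other way, at a mean log2 CPM of 3.61 ± 0.85 in KO and 8.90 ± 1.05 in WT.

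Naive and memory genes were called higher as a list (1 of 24 rose, Myb; 3 rose over the list alone; median log2 fold change 0.44, camera adjusted p = 0.028, adjusted p = 0.39 with an estimated correlation). The call on the naive and memory T cell list was lost with the library set as a term (median 0.32, camera adjusted p = 0.066) and within library numbers 4 to 8 (0.21, 0.37). With T cell receptor scaling the median turned to -0.13, but that scaling shifted the median of all genes by -0.76, which alone could turn the sign. The call was lost with that scaling (camera adjusted p = 0.095) and with the B cell score as a term (1.40, 0.054). It was also lost without KO replicate 2 (0.48, 0.051), WT replicate 1 (0.52, 0.090) or WT replicate 3 (0.45, 0.059). Myb, a transcription factor of progenitor cells, stood at 57.0 ± 26.8 CPM in KO and 6.14 ± 1.69 CPM in WT (log2 fold change 3.21, SE 0.51, edgeR adjusted p = 0.0090). Tcf7, Ccr7 and Il7r did not pass, with log2 fold changes of 0.94, 0.88 and -0.96. Mapk12, a p38 kinase, was among the largest rises and kept its call without any 1 library (104 ± 62.2 CPM in KO, 8.01 ± 3.75 CPM in WT, log2 fold change 3.69, edgeR adjusted p = 0.0090). Egr4 and Sh3gl3 had 2 counts each over the WT group. Their ratios of group totals were 1877 (95% counting interval 519 to 15501) and 1461 (404 to 12068), and both calls were lost in 6 of 10 fits without 1 library (adjusted p up to 0.13 for both). Their KO counts came mostly from library numbers 1 to 3, where Egr4 stood at 30.2 to 97.7 CPM and Sh3gl3 at 18.2 to 55.8 CPM, against 0.48 to 1.14 and 0.044 to 2.00 CPM in KO libraries 4 to 8. Within library numbers 4 to 8 the log2 fold change of Egr4 was 5.15 (edgeR adjusted p = 0.059), and KO replicate 1 held the highest Egr4 value. Such intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. The immunoglobulin share differed between the genotypes as well, at 0.125 ± 0.0358% in KO and 8.13 ± 6.52% in WT.

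Markers of other cell types differed between the genotypes. Of 21 B cell and plasma cell markers, 16 fell in KO and 0 rose; adjusted over the list alone, 20 fell (median log2 fold change -4.96, camera adjusted p = 1.0e-39, adjusted p = 0.030 with an estimated correlation). Igkc, the kappa light chain constant gene, stood at 116 ± 98.4 CPM in KO and 20737 ± 17709 CPM in WT, and Cd74, the class II invariant chain, at 750 ± 484 against 18510 ± 5749 CPM (edgeR adjusted p = 0.0029 and 0.0023). Of 24 myeloid and dendritic cell markers, 7 fell and 18 fell over the list alone (camera adjusted p = 1.4e-16, adjusted p = 0.061 with an estimated correlation). Lyz2 stood at 55.1 ± 49.1 CPM in KO and 2544 ± 2179 CPM in WT; its call was lost without WT replicate 4 (adjusted p = 0.057). Between 53 and 103 heavy chain variable segments had over 10 counts in a WT library, against 4 to 27 in a KO library (exact two-sided permutation p = 0.0095, the smallest that 6 against 4 libraries allow). Among CD8 and NK cell markers, Klrb1c rose (224 ± 38.8 CPM in KO, 32.03 ± 20.1 CPM in WT, edgeR adjusted p = 0.012, and 0.065 without WT replicate 4); the list of 7 was not called (1 rose and 2 fell over the list alone, camera adjusted p = 0.22). No melanoma marker passed (3 tested, camera adjusted p = 0.99). The 9 stromal, endothelial and red cell markers held no gene that passed, while the list was called higher (median log2 fold change 2.49, camera adjusted p = 0.027, adjusted p = 0.32 with an estimated correlation). That call on the stromal, endothelial and red cell markers was lost within library numbers 4 to 8 (median 1.38, camera adjusted p = 0.52) and without WT replicate 1 (1.85, 0.66).

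**Figure D3:**
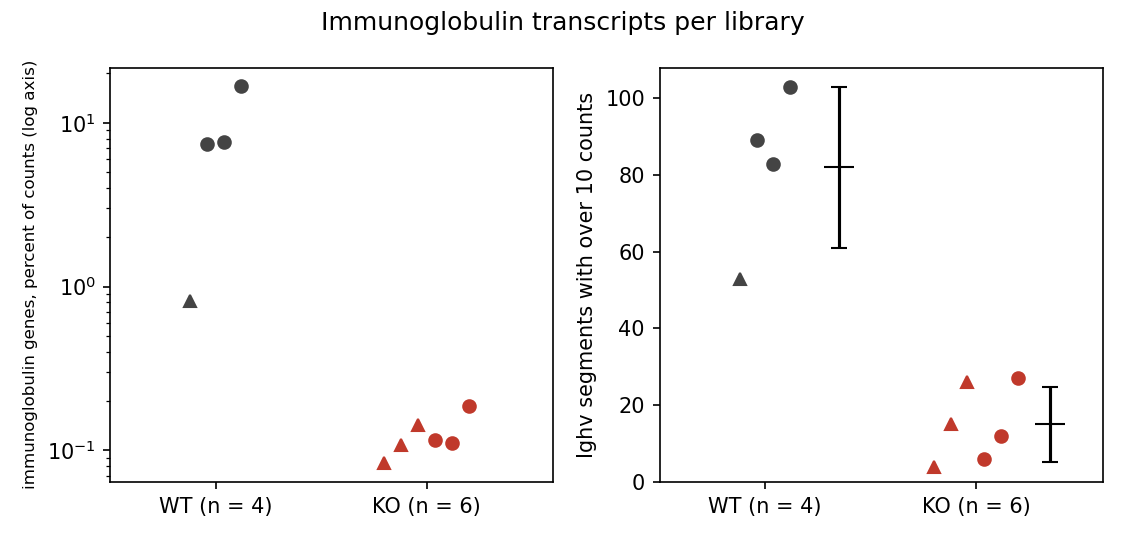
Percent of counts on immunoglobulin genes (left, log axis) and number of heavy chain variable segments with over 10 counts (right; black bars are mean and SD) in each library; triangles are library numbers 1 to 3 and circles 4 to 8. The 4 WT libraries lie between 0.815 and 16.7% and the 6 KO libraries between 0.0835 and 0.187%.

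The transgenic receptor was present in all 10 libraries. Trbv13-1 took 94.1 to 98.3% of the Trbv counts in WT and 98.1 to 99.0% in KO (exact two-sided permutation p = 0.019). The Trav14 family took 94.4 ± 0.391% of Trav counts in WT and 90.3 ± 6.23% in KO (exact two-sided permutation p = 0.32), with 81.6% in KO replicate 1. The KO libraries numbered 1 to 3 held 81.6 to 87.0% and those numbered 4 to 8 held 94.7 to 96.6%. Genes near the targeted locus were called about as often as others: 1 of 45 tested genes within 10 Mb of Tox passed, against 3.13% elsewhere (Fisher's exact two-sided p = 1). Near Ptprc, which encodes the congenic marker that told the cells apart (Ly5), 2 of 97 passed (Fisher's exact two-sided p = 0.77). Within library numbers 4 to 8 it was 15 of 102, or 14.7% against 7.97% elsewhere (Fisher's exact two-sided p = 0.025). Ptprc itself did not pass (log2 fold change -2.12, SE 0.74, edgeR adjusted p = 0.17). It fell within library numbers 4 to 8 (-1.84, edgeR adjusted p = 0.035) and without WT replicate 1 (-2.50, edgeR adjusted p = 0.024).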

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

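The tests of the immunoglobulin transcripts and of the library set were chosen after those results were seen, and the corrections for GC content, T cell receptor genes and the B cell score were added after the data were seen but before their own values were.

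In 12 of 15 results in which 1 library lay far from the others of its genotype, that library was WT replicate 1, the only WT library numbered 1 to 3. Its log2 CPM was 7.28 for Ccr7 (other WT libraries 9.05 to 9.30), -2.57 for Bcl6 (5.45 to 6.20), 4.50 for Foxp3 (6.33 to 6.41), 2.80 for Itgae (5.17 to 5.62), 3.68 for Ms4a1 (8.40 to 9.04) and -4.38 for Pmel (2.10 to 2.80). The mean log2 CPM in that library was 2.11 for the TH2 and TH17 list (other WT libraries 3.89 to 4.08), 4.54 for chemokine receptors and trafficking (6.04 to 6.22) and 4.80 for interferon gamma and antigen presentation (6.58 to 6.80). It was 7.33 for the B cell and plasma cell markers (9.30 to 9.56) and 0.53 for the CD8 and NK cell markers (3.33 to 3.82). WT replicate 1 had 14365 genes detected and the other WT libraries 19101 to 19775. The other results were Prf1 in KO replicate 3 (-3.03 against 1.03 to 2.90), Ciita in KO replicate 1 (-2.91 against 1.77 to 3.70) and Egr4 in WT replicate 3 (-3.30 against -4.38 in the others, a difference of 2 counts). Chance alone gives about 10.7 such results among the 214 groups tested, and results from 1 library are not independent of each other.

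Immunoglobulin and B cell transcripts were higher in the WT libraries. Expression by the transferred T cells was argued against, since each WT library held at least 53 heavy chain variable segments with over 10 counts, more than any KO library, and T cells do not rearrange these genes. Cells or RNA of other types in the WT libraries stayed open as a candidate source (WT means 20737 CPM for Igkc and 18510 CPM for Cd74). Of 21 B cell and plasma cell markers, 16 had every WT library above every KO library. That count restates the pattern and does not test it. The sort on CD4 and Ly5.1 should have removed such cells, but host B6 cells carry Ly5.2, which the KO gate excluded and the WT gate required, so the gates differed in what they would let through; whether cells entered attached to others, by gate or as free RNA was not tested.

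The TH1 effector list was lower in KO, and 1 of 100 splits of the libraries, the real one, gave a camera p as small (9.2e-08, smallest other 1.0e-06). That argued against chance if the libraries are independent, which the labels do not show. A GC trend and the library set were argued against as the whole cause, with camera adjusted p = 3.5e-07 and 2.4e-06 after correction. With an estimated correlation the unadjusted camera p was 0.018 and 0.015, little changed from 0.014 without correction. Adjusted over the lists, that 0.014 was 0.066. Cells of other types stayed open: with the B cell score as a term the camera p was 1.4e-04 and the median -1.88, which met the bound set beforehand, as did each fit without 1 library (largest p 0.011, without KO replicate 5, where the median was -2.77). That bound asked too little of this design. The scores of the genotypes do not overlap (2.08 to 4.25 in KO, 7.33 to 9.56 in WT). With the term in the fit even Tox lost its call (-4.18, adjusted p = 0.68), and the score covers B cells alone. With an estimated correlation the unadjusted camera p was 0.068, a condition added after these values were seen and applied to all 3 corrections. Loss of TOX and the gate remain possible causes that the design cannot separate.

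The genes higher in KO numbered 61, and 1 of 100 splits, the real one, gave as many (highest other 2). For the 384 genes lower it was also 1 of 100 (highest other 96), the fewest possible with the real split among them. These splits argued against chance if the libraries are independent, which the labels do not show. For the 15 lists called, 4 of 100 splits gave as many, since 3 other splits also reached 15. The other splits drawn called at least 1 list each. A group of 3 KO and 3 WT libraries called 13, with a camera p of 2.0e-05 for the TH1 effector list. Camera at the preset correlation thus called lists without the real grouping, so its calls alone are weak evidence. A GC trend was argued against as the whole cause, since 33 of the 61 genes stayed called with it removed, at a median log2 fold change of 1.46 against 1.99. Dilution of T cell RNA by other cells in the WT libraries may explain part of the pattern and stayed open: scaled to T cell receptor complex genes, 14 of the 61 stayed called, all 61 stayed above 0, and their median was 1.17. Loss of TOX and the gate remain untested as causes.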

How the results depend on the processing

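The alternatives with the library set, GC content, T cell receptor genes and the B cell score were chosen after the data were seen. For lists the value given is the median log2 fold change, while a reversal refers to camera's direction, so the median can keep its sign. The cause of each change was not tested unless stated. Of 3504 values of genes and lists, 2806 kept direction and side of the threshold, 532 lost the threshold, 57 gained it and 109 reversed.

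The TH1 effector list stayed lower in 35 alternatives (median -3.45 to -1.69, camera adjusted p 3.5e-08 to 0.0017); with an estimated correlation its median of -2.58 had an adjusted p of 0.066, and 1 list was called in place of 15. Genes higher in KO numbered 39 with no filter on low counts, 613 with DESeq2 (999 lower), 204 with limma-voom (680 lower), 2562 with quality weights (2768 lower), 23 for a fold above 1.5, 206 with 1 surrogate variable and 104 with the gene length trend removed. With adjusted p under 0.01 they numbered 7 (121 lower), and with named genes only, where fewer genes were tested, 209 were lower. Upper-quartile factors shifted the median of all genes by -0.13. Leaving out each library gave 10 to 443 genes higher and 143 to 1201 lower.

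With the library set as covariate 116 genes were higher. Libraries 4 to 8 only gave 121 higher and 1033 lower, and libraries 1 to 3 only, with 1 WT library assumed to vary like the others, 316 and 79. In libraries 4 to 8 only, 14.7% of the genes in the chromosome neighbourhood of Ptprc passed against 7.97% elsewhere (Fisher's exact p = 0.025) and the Trav14 family share was 1.23 points higher in KO (exact permutation p = 0.20). Scaled to T cell receptor complex genes, 20 were higher and 1671 lower. With the B cell score as covariate edgeR called 0 higher and 0 lower (617 and 366 at unadjusted p under 0.05; DESeq2 without it 613 and 999), 5 lists, and Tox at -4.18 (adjusted p = 0.68).

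The replicate block was checked by correlating WT and KO libraries of 1 number, after the mean of each gene within its genotype was subtracted. Title numbers gave r of 0.36, -0.34, -0.34 and 0.40. The positive r came from pairs within 1 library set and the negative r from pairs across the sets. They therefore cannot show whether the replicates are paired. Library numbers give only 2 pairs (0.42 and 0.19), each within 1 library set, so the same limit holds. With the block by title number edgeR called 0 higher and 0 lower (1213 and 1086 at unadjusted p under 0.05) and Tox was -3.27 (adjusted p = 0.12); by library number 0 and 0 (73 and 379) with Tox at -2.73 (adjusted p = 1). As a random effect (correlation 0.21) the block gave 258 and 757. Values that reversed with the block by title number were list: exhaustion-associated regulators 0.16, list: oxidative phosphorylation -0.23, Tbx21 0.86 and Pmel 0.44. By library number they were list: type I interferon response 0.089, list: apoptosis regulators 0.012, list: melanoma markers 1.23, Il7r 0.055, Bcl6 1.55 and Pmel 3.34. As a random effect they were list: exhaustion-associated regulators 0.27, list: heat shock and stress 0.14, list: melanoma markers 0.67, Tbx21 0.050, Bcl6 0.0062 and Pmel 1.66.

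Reversed list medians under other alternatives were as follows. For list: exhaustion-associated regulators they were 0.0019 with RLE factors, 0.068 with total counts, -0.085 with upper-quartile factors, 0.12 with no filter, 0.0048 with DESeq2, 0.25 with limma-voom, -0.022 with quality weights, 0.13 with the library set and 0.16 in libraries 4 to 8. For list: heat shock and stress they were -0.26 with no filter, 0.24 with limma-voom, 0.45 with quality weights, -0.028 with the length trend removed and 0.56 in libraries 4 to 8. For list: glycolysis they were -0.14 with no filter and 0.042 in libraries 4 to 8. For list: oxidative phosphorylation they were -0.23 with no filter, -0.19 with quality weights, 0.060 with the length trend removed and -0.040 in libraries 4 to 8. For list: apoptosis regulators they were -0.032 with no filter and -0.12 in libraries 4 to 8, and for list: ribosomal proteins -0.29 in libraries 4 to 8. For list: melanoma markers they were -0.025 with a mean count of at least 50, 0.61 with limma-voom, 0.38 with 1 surrogate variable, 0.49 with the library set, -0.26 in libraries 4 to 8, 6.84 in libraries 1 to 3, 0.25 with the library set and GC, -1.10 with T cell receptor scaling and 5.00 with the B cell score. For list: costimulatory receptors and TNF family they were -0.22 in libraries 1 to 3, -0.61 with T cell receptor scaling and -0.68 with the B cell score. For list: type I interferon response and list: CD8 and NK cell markers they were 1.18 and 1.26 in libraries 1 to 3 and 0.76 and 4.44 with the B cell score.

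Reversed log2 fold changes of genes, of which none passed in that alternative, were as follows. Tbx21 was 0.16 with limma-voom, 1.37 with quality weights and 0.043 in libraries 4 to 8. Pmel was 1.48 with limma-voom, 1.64 with 1 surrogate variable (Bcl6 0.28), 0.60 with the library set and 0.25 with the library set and GC (Il7r 0.19). With quality weights Tox2 was 0.077 and Pecam1 -0.011. In libraries 1 to 3 only, Lag3 was -0.026, Ptprc 0.37, Il7r 0.63, Bcl6 5.87 and Pmel 9.94. With T cell receptor scaling Gpnmb was -0.61 and Pecam1 -0.68. With the B cell score as covariate Lag3 was -3.57, Ptprc 0.81, Gzmb 2.87, Il7r 1.08, Itgae 0.67, Tmem176b 1.71, Ciita 1.29, Fkbp11 1.04, Ms4a1 7.30, Mzb1 0.88, Igkc 0.35, Ctss 0.55, Gpnmb -1.28 and Pmel 5.00.

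Without 1 library in turn, values that reversed at least once ranged from -0.038 to 0.29 for list: exhaustion-associated regulators, -0.63 to 0.40 for list: heat shock and stress, -0.48 to 0.054 for list: oxidative phosphorylation and -0.93 to -0.034 for list: melanoma markers. They ranged from -0.37 to -0.016 for list: glycolysis, -0.56 to -0.19 for list: ribosomal proteins, -1.14 to 1.74 for Tbx21, -0.070 to 1.53 for Gpnmb, -0.10 to 0.53 for Pecam1 and -0.64 to 0.18 for Pmel. Without WT replicate 1 the oxidative phosphorylation list was called higher (median 0.054, adjusted p = 0.019) and Tbx21 was 1.74 (adjusted p = 0.28). The oxidative phosphorylation list was called lower with the B cell score as covariate (-1.24, adjusted p = 3.5e-04) and with T cell receptor scaling (-0.93, adjusted p = 0.018). In libraries 1 to 3 only, with 1 WT library, its median was -0.94. The calls on the oxidative phosphorylation list used the preset correlation between genes. In all libraries its estimated correlation was 0.55, with a camera adjusted p of 0.99, so these calls alone are weak evidence.

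Depth was at least 31939816 counts per library, and the common dispersion was 0.974.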

Other observations

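The values here come from lists fixed before the data were examined, and no explanation was tested on them; the alternatives with the library set, GC content, T cell receptor genes and the B cell score were chosen after the data were seen.

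The type I interferon response list was called lower in KO (2 of 37 fell, Oasl1 and Parp14, also 2 adjusted over the list alone, camera adjusted p = 0.0081, adjusted p = 0.59 with an estimated correlation). That call was lost with the library set as a term (median -0.43, camera adjusted p = 0.066) and without WT replicate 4 (-0.49, 0.11). Within library numbers 1 to 3, which hold 1 WT library, the list's direction turned to higher, with a median of 1.18 against -0.73 in all libraries. With the B cell score as a term it also turned, to 0.76 (camera adjusted p = 0.068). The call on Oasl1 was lost in 8 and that on Parp14 in 9 of the 10 fits without 1 library (adjusted p up to 0.23 and 0.14). The cytokine receptors and STAT signalling list was called higher (1 of 33 rose, Il27ra; 2 over the list alone; median log2 fold change 0.21, camera adjusted p = 0.040, adjusted p = 0.45 with an estimated correlation). Its call was lost within library numbers 4 to 8 (median 0.16, camera adjusted p = 0.10), with the GC trend removed (0.22, 0.072), with T cell receptor scaling (-0.50, 0.14) and with the B cell score as a term (0.73, 0.32). It was also lost without KO replicate 1 (0.22, 0.061), 4 (0.30, 0.10), 5 (0.29, 0.065) or 6 (0.20, 0.059). Without WT replicate 1 or 2 the medians were 0.17 and 0.23 (0.14 and 0.055). Il27ra, a receptor chain for interleukin 27, stood at 1424 ± 228 CPM in KO and 346 ± 176 CPM in WT (log2 fold change 2.04, edgeR adjusted p = 0.0092, and 0.061 without WT replicate 4).

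Other lists were not called. In the costimulatory receptors and TNF family list Slamf7 fell (1 of 19; 2 rose and 2 fell over the list alone; camera adjusted p = 0.43), a call lost in 6 of the 10 fits without 1 library (adjusted p up to 0.13). In the heat shock and stress list Hmox1, heme oxygenase, fell (1 of 15, also 1 over the list alone; camera adjusted p = 0.89). In the interferon gamma and antigen presentation list Ciita, the class II regulator, fell (1 of 30; 1 rose and 1 fell over the list alone; camera adjusted p = 0.41); its call was lost in 6 of the 10 fits without 1 library (adjusted p up to 0.074). That list's median log2 fold change was -0.22 while camera's direction was up. In the cholesterol synthesis list Sc5d fell (1 of 24, also 1 over the list alone; camera adjusted p = 0.38), a call lost in 7 of the 10 fits without 1 library (adjusted p up to 0.16).

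No member of the glycolysis, oxidative phosphorylation, MYC and ribosome biogenesis, apoptosis regulators or ribosomal proteins lists passed the edgeR test. Their median log2 fold changes were -0.23, -0.29, -0.033, -0.080 and -0.38, with camera adjusted p of 0.63, 0.86, 0.40, 0.64 and 0.067. The ribosomal proteins list was called lower without KO replicate 3, KO replicate 6 or WT replicate 3 (medians -0.40, -0.45 and -0.56, camera adjusted p = 0.034, 0.027 and 0.0010). It was also called lower with the library set as a term (-0.46, 0.0044), with the GC trend removed (-0.60, 0.0014) and with both (-0.59, 1.5e-04). The same held with T cell receptor scaling (-1.06, 1.2e-06), but not within library numbers 4 to 8 (-0.29, 0.99). Within numbers 1 to 3, with 1 WT library, the median of the ribosomal proteins list was -0.72. The median of the oxidative phosphorylation list was -0.94 within library numbers 1 to 3, which hold 1 WT library. That list was called lower with the B cell score as a term (-1.24, 3.5e-04) and with T cell receptor scaling (-0.93, 0.018). Without WT replicate 1 it was called higher (0.054, 0.019). The calls on both lists used the preset correlation between genes. In all libraries the estimated correlation was 0.67 for ribosomal proteins and 0.55 for oxidative phosphorylation. The camera adjusted p with it was 0.77 and 0.99, so these calls alone are weak evidence. Adjusted over the list alone, 1 glycolysis gene fell. For the MYC and ribosome biogenesis list camera's direction was up while the median was negative. The exhaustion-associated regulators had a median of 0.097 and a mean of -0.61.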
